A study of Sus scrofa with 31 samples.

How the data were processed

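Pig (Sus scrofa) myocardium was profiled by RNA sequencing in 2 arms. In arm 1, hearts of 6 pigs were biopsied at 0, 12, 24 and 48 h of storage, 3 of them under the condition labelled SCS (pigs 1, 3 and 5) and 3 under the condition labelled HOPE (pigs 2, 4 and 6), which gave 24 libraries. In arm 2, 7 libraries came from hearts that went through storage and then 2 h of normothermic machine perfusion (NMP), with 2 libraries each after 3, 24 and 48 h of HOPE and 1 library after 24 h of SCS. The labels do not spell out SCS and HOPE; the usual readings in heart preservation are static cold storage and hypothermic oxygenated perfusion. Groups, times and pig numbers were taken from the sample titles and characteristics.

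The deposited arm 1 table held normalized counts, that is, a signal in which the authors had divided gene counts by 1 size factor per library, per the file header and its values. In all 24 columns 100% of the values were whole multiples of 1 step per library at a tolerance of 1e-06, so whole reads were recovered; they came to 19722065 to 35099406 per library. The deposited arm 2 table is also called normalized counts in its name, but its columns each summed to the same round total and gave no whole reads, so the authors' values were read as TPM, that is, already divided by gene length and total. Depth is therefore unknown in arm 2, and count tests could not be run there. Spike-in RNA was added in arm 2, per the labels' protocols, and spike-in scaling was not used here. The submitters' processing notes name FastQC, bcl2fastq 2.17, Trimmomatic 0.36, HISAT2 2.2.1, STAR 2.5.2b, featureCounts 2.0.6, Subread 1.5.2, DESeq2 and the Sscrofa11.1 build, without saying which tool served which arm. Arm 1 used a stranded poly(A) kit and arm 2 another poly(A) kit, per the labels' protocols; whether counting used strand is not given in the sources used here. Because kits and units differed, tests were made only within an arm. Another 11 columns of the arm 2 table match no sample here and were not used.

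Gene IDs were used as deposited. Symbols came from each arm's own table for 14365 arm 1 and 13143 arm 2 genes. For another 109 arm 1 genes they came from a reference table. For another 786 arm 2 genes they came from the arm 1 table where it named the same ID, and otherwise from the reference table. The tables listed 21313 and 25149 genes, of which 11848 IDs were in both, and 8224 arm 2 genes were listed at 0 in all 7 libraries. Many list genes were not found in arm 2. A symbol can stand for different gene IDs in the 2 arms: the MYH7 values are those of ENSSSCG00000053614 in arm 1 and of ENSSSCG00000002029 in arm 2. Gene positions were taken, by symbol, from the RefSeq table of Sscrofa11.1.

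Each arm was fitted once over all its libraries with limma 3.58.1 (lmFit, contrasts and eBayes with a mean trend) in R 4.3.3 on log2(value + 1). Fold changes are on this scale, which understates changes of low genes. Genes with a mean of at least 10 over the libraries of the arm were tested, 14141 in arm 1 and 4388 in arm 2. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The comparisons were each storage time against 0 h within SCS and within HOPE, HOPE against SCS at each time, the difference in change from 0 h between HOPE and SCS, and, in arm 2, the HOPE storage times against each other and SCS 24 h against HOPE 24 h. The arm 2 fit had 3 residual degrees of freedom, and its lone SCS library was assumed to vary like the other groups. The design had been fixed for normalized counts in both arms; the pseudocount of 1 and the minimum of 10 were kept for the TPM values.

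The same pig gave all 4 arm 1 biopsies of a series, so the pig was also fitted as a replicate block: as a fixed term for changes within pigs, and as a random term with an estimated correlation of 0.44 for HOPE against SCS. Deviations from the group means correlated in every same-pig pair, with r of 0.232 to 0.72 in 18 SCS pairs and 0.399 to 0.73 in 18 HOPE pairs. Blocked values are given in arm 1 where they changed a call or a count of calls by over 1.5 times. In arm 2, r was 0.09 to 0.384 in 6 pairs of equal numbers and -0.384 to -0.09 in 6 other pairs. With 2 libraries per group these values mirror each other, so they cannot decide whether equal numbers pair. The labels do not say so either, and the arm 2 block is given only among the alternatives.

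Before the data were examined, 24 pathway lists and 13 cell type lists were fixed. A list with at least 4 tested members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, and again with a correlation estimated from the data. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Genes were named by a rule fixed at the same time. In the main comparisons these were the 6 highest and 6 lowest log2 fold changes among genes that passed, had a mean of at least 100, a symbol, and no overlap between the libraries compared; in other comparisons they were the 2 highest and 2 lowest. For each list described, up to 4 members with the smallest p were named, and where no gene passed, up to 3 genes with a symbol and the smallest p. Library measures were compared by two-sided exact permutation tests, for which 3 pigs against 3 cannot go below p = 0.1.

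Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, scaling of the arm 1 libraries to the same total (total-count scaling), quantile normalization, fits of only the groups compared, leaving out each pig or library in turn, the replicate block, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Some were added after the data were seen: the block combined with leaving out a pig or with edgeR, leaving out single libraries, the block combined with an estimated list correlation, a mean of at least 1 TPM, and rescaling arm 2 without its most abundant genes. Figures were drawn with matplotlib 3.10.9. The tests were checked on simulated data with 50 changed genes at each fold among the genes tested. Each simulated library was drawn independently, without a pig effect, whereas biopsies of the same pig were correlated in the data. The recoveries and false calls with and without the block therefore do not tell how either fit behaves on repeated biopsies. For SCS 48 h against 0 h over 14141 genes, limma recovered 34%, 78%, 92% and 92% of genes changed by 2, 4, 8 and 16 times, with 18 false calls. The blocked fit recovered 30%, 78%, 86% and 94%, with 15 false calls. edgeR recovered 32%, 78%, 90% and 92%, with 11 false calls. DESeq2 recovered 38%, 88%, 96% and 96%, with the most false calls, 37. For the difference in change at 48 h, limma recovered only 10%, 48%, 78% and 92%, with 6 false calls. For HOPE 24 h against 3 h with NMP over 4388 genes, limma recovered 20%, 90%, 98% and 100%, with 24 false calls.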

Results

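The arm 1 libraries followed 6 pig hearts through storage, with 3 hearts in SCS and 3 in HOPE at 0, 12, 24 and 48 h, and held 19722065 to 35099406 recovered reads each. The 7 arm 2 libraries were taken after storage and a further 2 h of NMP, in which warm perfusate is pumped through the heart. Pigs were the replicates in arm 1; the arm 2 labels give groups and numbers, so its p-values measure the spread between those samples. The labels give cardiomyocytes as the cell type, but whole myocardial biopsies were sequenced. The design asks how the myocardial transcriptome changes with storage time, whether it changes otherwise in HOPE than in SCS, and what is seen once the stored heart has been warmed. Fold changes below are log2 values ± SE, and group levels are means ± SD.

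The 13 mitochondrially encoded genes, which specify subunits of the respiratory chain and ATP synthase, took a growing share of the normalised counts in SCS hearts. Their share was 42.4% ± 8.90 at 0 h, 47.7% ± 12.9 at 12 h, 49.5% ± 11.05 at 24 h and 63.5% ± 17.4 at 48 h (SD, n = 3). In HOPE hearts it was 35.8% ± 3.31, 32.0% ± 2.41, 34.3% ± 2.201 and 30.8% ± 1.54 at the same times (SD, n = 3). Between 0 and 48 h the share moved by 12.2, 21.3 and 29.9 percentage points in SCS pigs 1, 3 and 5, and by -1.42, -5.63 and -7.98 points in HOPE pigs 2, 4 and 6. The changes of the 3 SCS and 3 HOPE pigs did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows (Benjamini-Hochberg adjusted 0.233 over 35 library tests). In the SCS 48 h library of pig 5 the share was 82.4%. Beta-globin (HBB, chromosome 9, positions 4800683 to 4801941, protein coding) was at 89.4 to 1892 normalised counts in the 9 HOPE libraries after 0 h and at most 71.5 in the other 15.

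**Figure D1:**
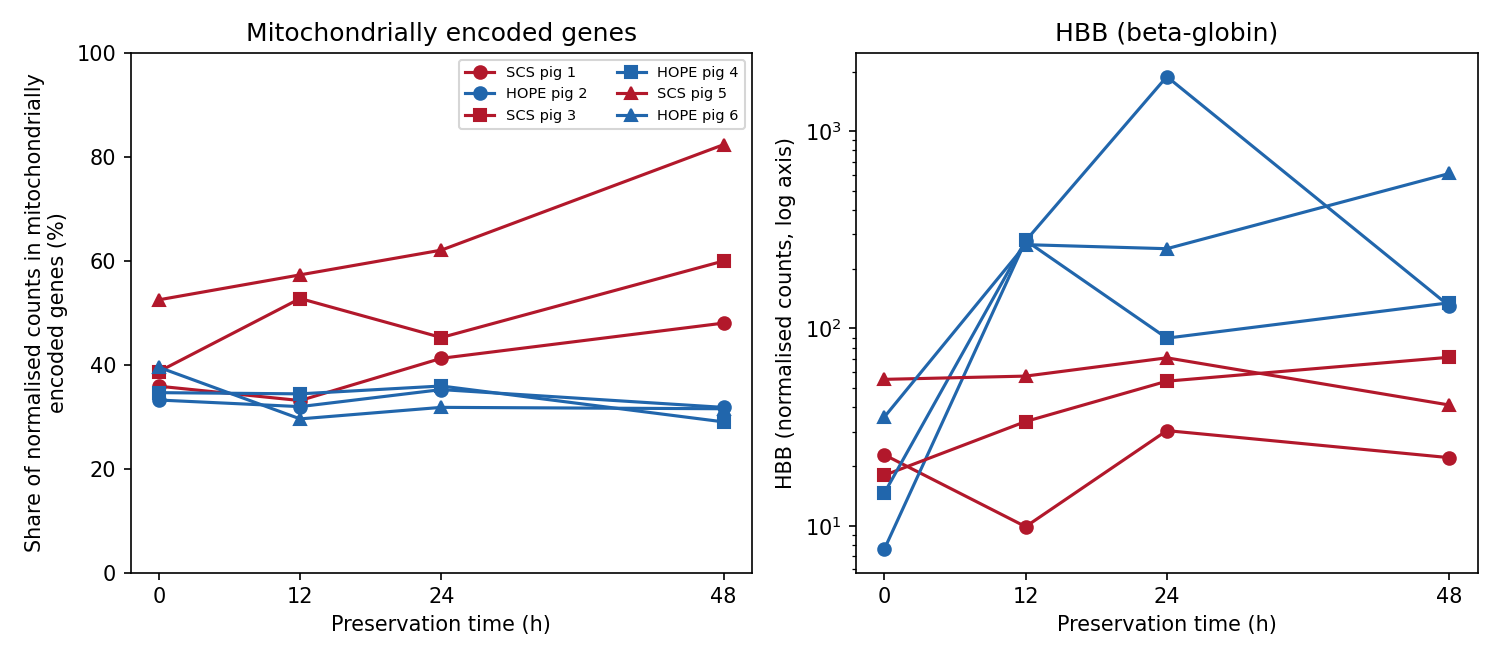
Share of normalised counts in mitochondrially encoded genes (%, left) and HBB in normalised counts on a log axis (right) against preservation time in hours, 1 line per pig, red for SCS and blue for HOPE. The share at 48 h was 48.0% to 82.4% in the SCS pigs and 29.0% to 31.8% in the HOPE pigs, and HBB lay between 89.4 and 1892 in HOPE hearts after 0 h.

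After 48 h of SCS, mitochondrially encoded transcripts were higher than at 0 h, when each heart was compared with its own 0 h biopsy. Nuclear-encoded respiratory chain genes did not rise alike, with medians of 0.57, -0.05 and -0.64 in pigs 1, 3 and 5. With the pig as a block, limma called 153 genes higher and 155 lower. Among them, ND4L changed by 1.78 ± 0.29 (limma with the block, adjusted p = 0.013), ND5 by 1.70 ± 0.38 (adjusted p = 0.0331), and ND4 by 1.58 ± 0.37 (adjusted p = 0.0392; -0.03 with quantile normalization); all are complex I subunits. The Golgi tethering protein GOLGA4, the splicing-related cyclophilin PPIG and the cell polarity protein PARD3B changed by 1.37 ± 0.31, 1.25 ± 0.21 and 1.21 ± 0.28 (limma with the block, adjusted p = 0.0347, 0.013 and 0.0371). ND4L (positions 11069 to 11365 of the mitochondrial genome) overlaps ND4 (11359 to 12736), and reads of such neighbours and of nuclear copies of mitochondrial DNA may have been split between them in counting. The caveolar coat protein CAV1 (chromosome 18, 29648120 to 29682451) fell by 2.36 ± 0.47, from 3241 ± 572 to 1063 ± 1210 normalised counts (SD, n = 3; limma with the block, adjusted p = 0.0228). The thrombin receptor F2R changed by -1.91 ± 0.38 and the vascular ligand EFNB2 by -1.75 ± 0.39 (limma with the block, adjusted p = 0.0232 and 0.0324). The chemokine CX3CL1, MCC and the gap junction protein GJA5 changed by -1.73 ± 0.38, -1.68 ± 0.38 and -1.65 ± 0.40 (limma with the block, adjusted p = 0.0317, 0.0347 and 0.0411).

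By list, the mitochondrially encoded genes had a median of 1.55 at 48 h of SCS, 0.58 with total-count scaling, with 13 of 13 members positive (camera, adjusted p = 3.08e-11). With an estimated correlation the adjusted p was 0.678, and 0.293 with the block as well. With the block 10 of the 13 passed over all genes, ND6 at 1.49 among them, and 13 adjusted over the list alone; without it 0 and 5 did. Ribosomal proteins, structural parts of the cytosolic ribosome, had a median of 0.42, which turned to -0.56 with total-count scaling (camera, adjusted p = 1.46e-11; adjusted p = 0.941 with an estimated correlation). With the block 15 of 41 ribosomal proteins passed, and 32 did adjusted over the list alone. RPL35, RPL24, RPL14 and RPS25 were among them at 0.79, 0.67, 0.67 and 0.52, and at -0.19, -0.31, -0.31 and -0.46 with total-count scaling; their many pseudogenes can share reads. Endothelial markers had a median of -0.74, -1.72 with total-count scaling (camera, adjusted p = 0.031; adjusted p = 0.941 with an estimated correlation). With the block, 1 of 14 passed, the endothelial junction protein PECAM1 at -1.18. The growth factor receptors FLT1, TEK and KDR were at -1.28, -1.05 and -0.96 and did not pass. Adjusted over the list alone, with the block, 7 endothelial markers were lower and 1 higher. Interferon-induced genes had a median of -0.43 (camera, adjusted p = 0.043; adjusted p = 0.941 with an estimated correlation). The list did not pass with total-count scaling (-1.41, adjusted p = 0.118) or quantile normalization (-0.40, adjusted p = 0.0927). With the block RSAD2 and MX2, both antiviral effectors, passed at -1.70 and -1.22, while HERC5 (-1.08) did not. Adjusted over the list alone, with the block, 7 of 22 were lower and 1 higher. Within pigs 1, 3 and 5 the endothelial medians were -1.96, -0.11 and 0.13 and the interferon medians -1.23, -0.09 and 0.16, so the falls lay mostly in pig 1. In pig 1 the median was 0.62 for sarcomere genes, 0.84 for ventricular cardiomyocyte markers and 0.52 for tricarboxylic acid cycle genes, all 3 the highest of the SCS pigs.

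Without the block, limma called 0 genes for SCS 48 h against 0 h (1142 at an unadjusted p under 0.05), edgeR called 0 and DESeq2 22. The smallest p belonged to PPIG at 1.25, CD38 at -4.05 and ENTPD7 at -1.49, each with a limma adjusted p of 0.364. The blocked count of 308 became 0 without pig 5 or without its 48 h library alone, 329 without pig 1 and 597 without pig 3. Total-count scaling, which charges the mitochondrial reads to all other genes, called 5553 genes without the block, 0.108% of them higher.

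At 24 h of SCS, mitochondrially encoded genes had a median of 0.52 (camera, adjusted p = 0.00906), ribosomal proteins of 0.39 (adjusted p = 1.04e-13) and fibroblast markers of 0.49 (adjusted p = 3.45e-09). The adjusted p with an estimated correlation were 0.924, 0.753 and 0.496, and the medians with total-count scaling 0.17, 0.04 and 0.14. All 3 lists were positive in 3 of 3 pigs at 24 h, and mitochondrially encoded genes had a median of 0.43 at 12 h (camera, adjusted p = 0.0159; 0.909 with an estimated correlation), with 2 of 3 pigs positive. Limma called 0 genes at 12 h (161 at an unadjusted p under 0.05) and 0 at 24 h (482), with or without the block, and edgeR and DESeq2 called 0 at both times. The smallest p at 12 h belonged to PTPRZ1 (-1.62), JRKL (-0.74) and ZBTB34 (-0.68), each with a limma adjusted p of 1, and at 24 h to SLC24A1 (1.82), BSN (-2.59) and FLVCR1 (-1.28), each at 0.999.

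In HOPE hearts, markers of T and natural killer (NK) cells were lower and red cell transcripts higher than at 0 h at each later time. The 12 T and NK markers had a median of -0.95 at 12 h, -0.72 at 24 h and -0.93 at 48 h, with all 12 negative each time (camera, adjusted p = 3.86e-15, 3.08e-09 and 2.02e-15). The adjusted p with an estimated correlation were 0.0613, 0.339 and 0.057, and 0.0147, 0.0722 and 0.0125 when the block was added. Within pigs 2, 4 and 6 the medians were -0.34, -0.79 and -1.37 at 12 h, -0.41, -0.38 and -1.56 at 24 h and -0.64, -1.03 and -1.31 at 48 h. Pig 6, the lowest each time, had the most GNLY at 0 h (589 normalised counts against 256 and 204), and its endothelial medians were also negative (-0.64, -0.78 and -0.57). At 48 h KLRK1, an activating NK receptor, was at -1.70 ± 0.44, CD2, a T cell adhesion protein, at -1.36 ± 0.40, and the cytotoxic granule genes GNLY and NKG7 at -1.24 ± 0.46 and -0.69 ± 0.31. Over all genes 0 of these markers passed; adjusted over the list alone 2 did, and 7 with the block. At 12 h GNLY, KLRK1, LCK and CD5 were at -1.58, -1.21, -0.96 and -1.11, and at 24 h KLRK1, CD8A, GNLY and CD5 were at -1.30, -1.78, -1.15 and -0.998. At 48 h CX3CR1, the fractalkine receptor of NK cells and monocytes, went from 121 ± 5.53 to 42.4 ± 13.7 normalised counts (SD, n = 3). It was the single gene called with the block, at -1.54 (limma, adjusted p = 0.0187), and was named after its values were seen; this call ended without pig 2, 4 or 6 and without the 0 h library of pig 6.

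HBB was at 19.3 ± 14.6 normalised counts at 0 h of HOPE, 274.7 ± 7.46 at 12 h, 745 ± 997 at 24 h and 292 ± 276 at 48 h (SD, n = 3). Its log2 fold changes were 4.02 ± 0.86, 4.37 ± 0.86 and 3.70 ± 0.86, with limma adjusted p of 1, 0.783 and 0.839, and reads of other globin genes may be counted with it. ALAS2, which starts heme synthesis in red cell precursors, was at 2.82 ± 0.85, 3.49 ± 0.85 and 2.53 ± 0.85 (limma adjusted p = 1, 0.999 and 1). Of the 3 red cell genes tested, 2 passed adjusted over the list alone at each time; EPB42 did not. Interferon-induced genes had medians of -0.44, -0.37 and -0.36 (camera, adjusted p = 1.39e-08, 0.000259 and 0.000523; 0.509, 0.66 and 0.776 with an estimated correlation), with CXCL10 at -0.98 and ISG15 at -0.64 at 48 h, neither passing. Within pigs 2, 4 and 6 the interferon medians were -0.20, -0.42 and -0.73 at 12 h, 0.06, -0.44 and -0.81 at 24 h and -0.12, -0.34 and -0.64 at 48 h. Genes of the tricarboxylic acid cycle had a median of 0.33 at 48 h (camera, adjusted p = 0.00156; 0.776 with an estimated correlation), with DLST at 0.59 and not passing. Within pigs 2, 4 and 6 the median was 0.12, 0.18 and 0.68, and the 0 h library of pig 6 had less MYH7 than those of pigs 2 and 4, at 179000 normalised counts against 528000 and 510000. Ribosomal proteins had a median of -0.17 at 48 h (camera, adjusted p = 0.00107, and 0.776 with an estimated correlation). Their medians were -0.08, -0.35 and -0.02 in pigs 2, 4 and 6, with 24 genes lower and 17 higher in pig 6.

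For HOPE, limma without the block called 0 genes at 12 h (75 at an unadjusted p under 0.05), 0 at 24 h (215) and 0 at 48 h (197). On the recovered reads edgeR called 0 at each time, while DESeq2 called 0, 4 and 2. Besides HBB and ALAS2, genes among the smallest p were GNLY at 12 h, CD27 at 24 h (-2.72) and PRKCB at 48 h (-1.19), with limma adjusted p of 1, 0.999 and 0.839.

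**Figure D2:**
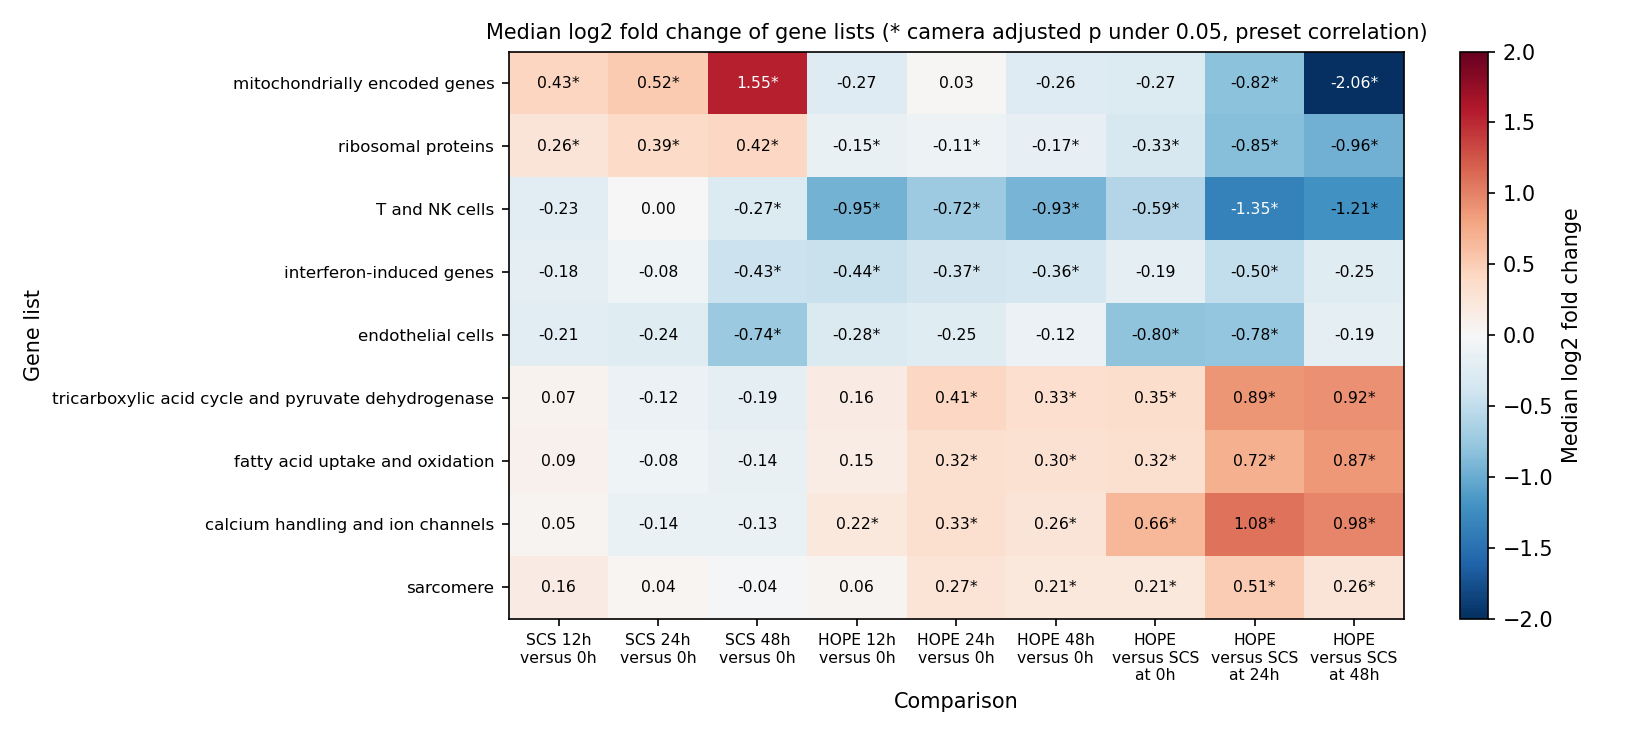
Median log2 fold change (colour and number) of 9 gene lists against 9 comparisons of arm 1, where an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Mitochondrially encoded genes stand at 1.55 for SCS at 48 h and -2.06 for HOPE against SCS at 48 h; the ribosomal protein medians at 48 h, 0.42 in SCS and -0.96 for HOPE against SCS, turn sign to -0.56 and 0.16 with total-count scaling.

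HOPE and SCS hearts already differed at 0 h in several lists. Endothelial markers had a median of -0.80 in HOPE against SCS (camera, adjusted p = 8.2e-05), T and NK markers of -0.59 (adjusted p = 0.000378), ribosomal proteins of -0.33, -0.20 with total-count scaling (adjusted p = 5.04e-05) and calcium handling and ion channel genes of 0.66 (adjusted p = 0.000508). The adjusted p with an estimated correlation were 0.634, 0.634, 0.658 and 0.634. The tight junction gene CLDN5 was at -1.53, the endothelial cadherin CDH5 at -0.94, the granzyme gene GZMB at -1.93, the T cell receptor chain CD3E at -1.14, the potassium channel KCNH2 at 0.97 and the calcium channel CACNA1C at 1.03, none passing over all genes. Limma called 0 genes at 0 h (1020 at an unadjusted p under 0.05), edgeR 0 and DESeq2 11. The smallest p belonged to the alarmin IL33 (-1.46), ARRDC4 (-1.33) and CYFIP2 (2.54), each with a limma adjusted p of 0.468. Without pig 6, limma called 337 genes at 0 h, and without its 0 h library alone 12.

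At 12 h the small GTPase of blood cells RAC2 (chromosome 5, 10553986 to 10571082) was lower by 1.59 ± 0.25 in HOPE than in SCS (limma, adjusted p = 0.0181). It was at 106 ± 21.3 normalised counts in HOPE and 320 ± 47.3 in SCS (SD, n = 3). At 0 h RAC2 already stood at 164, 165 and 235 in HOPE and at 339, 285 and 254 in SCS. The unnamed gene ENSSSCG00000012427, given because only 2 genes passed, was lower by 1.44 ± 0.21 in HOPE (limma, adjusted p = 0.0152). Together the 2 genes had a median of -1.52 at 12 h and -0.93 at 0 h. T and NK markers had a median of -1.32, -0.85 with total-count scaling (camera, adjusted p = 1.49e-08), and ribosomal proteins of -0.81, -0.34 with total-count scaling (adjusted p = 1.66e-17), with 9 of 12 and 31 of 41 lower adjusted over the list alone and 0 over all genes. The adjusted p with an estimated correlation were 0.401 and 0.464. The counts were 2 with limma (2311 at an unadjusted p under 0.05), 6 with the block, 2 with edgeR and 86 with DESeq2; with the block the lipoprotein receptor LRP8 (2.88), LRIG1 (1.91) and MYL1 (-3.42) passed as well. The fit without the block treats the 4 biopsies of a pig as independent, and a fit of only the 6 libraries compared called 0 genes at 12, 24 and 48 h. With the block, a single correlation shared by all genes was used, and the comparison still rested on 3 pigs against 3. Without pig 6 limma called 1432 genes, and without pig 3 it called 0.

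At 24 h limma called 179 genes higher and 109 lower in HOPE than in SCS. The lipoprotein receptor LRP8 was higher by 3.01 ± 0.58 (241 ± 133 against 26.6 ± 9.11 normalised counts; SD, n = 3; limma, adjusted p = 0.0282) and COQ10A, a coenzyme Q binding protein, by 2.41 ± 0.60 (limma, adjusted p = 0.0446); at 0 h they were at 2.205 and 1.47 without passing. The calcium binding protein S100A6 and the cytotoxic protein GNLY differed by -2.15 ± 0.42 and -2.03 ± 0.46 (limma, adjusted p = 0.0282 and 0.0365). Calcium handling and ion channel genes had a median of 1.08 (camera, adjusted p = 2.08e-05; 0.462 with an estimated correlation). CACNA1C was higher by 1.86 as the 1 member that passed over all genes, and KCNH2 was at 1.08. Adjusted over the list alone 14 were higher. T and NK markers had a median of -1.35 (camera, adjusted p = 1.89e-07; 0.462 with an estimated correlation). Over all genes 3 passed, with GZMB, GNLY and NKG7 passing at -2.66, -2.03 and -1.19, KLRK1 at -1.68 not passing, and 11 of 12 lower adjusted over the list alone. Ribosomal proteins had a median of -0.85, -0.47 with total-count scaling (camera, adjusted p = 3.93e-15; 0.462 with an estimated correlation). Over all genes 2 passed, with RPS25 and RPL32 passing at -0.96 and -0.98, RPL35 at -1.03 and RPS18 at -1.13 not passing, 36 of 41 lower adjusted over the list alone, and 30 over all genes with the block. The block raised the count of genes from 288 to 1396. This larger count came from the same pigs and a single correlation for all genes, so it is not stronger evidence.

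At 48 h limma called 543 genes higher and 341 lower in HOPE, the most of the 4 times. CYFIP2, a regulator of actin, was higher by 2.59 ± 0.57 (1557 ± 953 against 240.6 ± 96.3 normalised counts; SD, n = 3; limma, adjusted p = 0.022) and the glutamine transporter SLC38A1 by 2.57 ± 0.73 (limma, adjusted p = 0.0442). At 0 h CYFIP2 was already at 2.54 and SLC38A1 at 1.63. The myosin light chain of fast skeletal muscle MYL1 (chromosome 15, 113038083 to 113051315) was lower by 3.71 ± 0.75 in HOPE (limma, adjusted p = 0.0167). It was at 68.9 ± 41.0 against 871 ± 445 normalised counts (SD, n = 3). S100A6 (chromosome 4, 96098264 to 96099686) differed by -2.57 ± 0.42 (limma, adjusted p = 0.00708). At 0 h MYL1 was already at -2.73 (63.3 to 206 normalised counts in HOPE, 516 to 1190 in SCS) and S100A6 at -0.92, neither passing. Mitochondrially encoded genes had a median of -2.06, -0.95 with total-count scaling, with 6 of 13 lower over all genes and 11 adjusted over the list alone (camera, adjusted p = 6.59e-08; 0.526 with an estimated correlation); ND4L, ND4, ND3 and ND5 passed at -2.43, -2.26, -2.07 and -2.195. Genes of the tricarboxylic acid cycle had a median of 0.92, 2.04 with total-count scaling (camera, adjusted p = 1.02e-05; 0.526 with an estimated correlation). Over all genes 2 of 20 passed, DLST at 1.68 among them, and adjusted over the list alone 10 did. The fatty acid list had a median of 0.87 (camera, adjusted p = 0.000712; 0.603 with an estimated correlation) and did not pass with total-count scaling (1.99, adjusted p = 0.067). The lipase LPL at 1.53 and the electron carrier ETFA at 1.40 passed, PPARA at 2.15 and CPT1B at 1.15 did not, and 6 passed adjusted over the list alone. Calcium handling genes had a median of 0.98, 2.09 with total-count scaling (camera, adjusted p = 0.00112; 0.526 with an estimated correlation). Over all genes 4 of 21 were higher, among them CACNA1C by 1.77 and KCNH2 by 1.35. Adjusted over the list alone 13 were higher and 2 lower. The cardiomyocyte gene MYH7 was at 1.48 (limma, adjusted p = 0.0728, and 0.039 with the block), with 440000 to 697000 normalised counts in HOPE and 155000 to 402000 in SCS. At 0 h MYH7 was at 179000 to 528000 in HOPE and 174000 to 309000 in SCS. T and NK markers had a median of -1.21, -0.12 with total-count scaling, with 6 of 12 lower over all genes and 8 adjusted over the list alone (camera, adjusted p = 4.41e-05; 0.526 with an estimated correlation). Among them were KLRK1 at -2.12, GNLY at -2.04, GZMB at -2.56 and CD2 at -1.39. Ribosomal proteins had a median of -0.96, 0.16 with total-count scaling, and 14 of 41 were lower over all genes and 36 adjusted over the list alone (camera, adjusted p = 3.64e-18; 0.526 with an estimated correlation). RPS25, RPL32, RPL35 and RPL24 passed at -1.13, -1.12, -1.31 and -1.06. Coagulation genes had a median of -0.16, 0.96 with total-count scaling (camera, adjusted p = 0.04; 0.676 with an estimated correlation), with SERPINE2, TFPI2, S100A10 and ANXA2 passing at -1.36, -1.23, -1.56 and -1.03.

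The counts of HOPE against SCS at 24 and 48 h moved with single pigs and included differences present at 0 h. Of the 288 genes at 24 h, 284 had the same sign at 0 h, and of the 884 at 48 h, 835 did. The median of the genes higher at 48 h was 1.09 at 48 h and 0.44 at 0 h, and that of the genes lower was -1.25 and -0.43. Without a pig, limma called 2 to 2721 genes at 24 h and 5 to 3282 at 48 h, with the highest counts without SCS pig 1 (2721 and 3282) or HOPE pig 6 (2406 and 3160), 2 and 57 without pig 3, 2 and 5 without pig 5, 7 and 10 without pig 2 and 2 and 11 without pig 4. Without the 48 h library of pig 5 the 48 h count was 14. On the recovered reads edgeR called 219 and 841, DESeq2 1521 and 1931, and the blocked 48 h count was 1628. With total-count scaling the counts were 4 at 24 h and 8122 at 48 h, 99.5% of the latter higher in HOPE against 61.4% without it.

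The change from 0 to 48 h itself differed between HOPE and SCS for 18 genes when pigs were compared with their own 0 h biopsy, 3 of them more positive in HOPE and 15 more negative. EZR, which links membrane and actin, differed by 1.18 ± 0.19 (limma with the block, adjusted p = 0.0331). The metalloproteinase inhibitor TIMP1 differed by -1.22 ± 0.22 (limma with the block, adjusted p = 0.0418), the autophagy regulator DEPP1 by -1.17 ± 0.22 (adjusted p = 0.0464), and ID1, an inhibitor of differentiation factors, by -1.05 ± 0.20 (adjusted p = 0.0483). The ribosomal proteins RPL37, RPL35 and RPL38 differed by -1.12 ± 0.19, -0.996 ± 0.17 and -0.96 ± 0.18 (limma with the block, adjusted p = 0.0348, 0.0348 and 0.0464), RPL38 by 0.03 with total-count scaling. By list, mitochondrially encoded genes differed by a median of -1.76, -0.77 with total-count scaling (camera, adjusted p = 7.36e-11; 0.887 with an estimated correlation), with ND4L, ND3, ND6 and ND4 at -1.75, -1.82, -1.85 and -1.76 and none passing. Ribosomal proteins differed by -0.58, 0.41 with total-count scaling (camera, adjusted p = 4.21e-15; 0.887 with an estimated correlation), where RPL24, RPS25 and RPL32 at -0.86, -0.77 and -0.74 did not pass and RPL35 and RPL37 were among 4 of 41 that did with the block. Tricarboxylic acid cycle genes differed by 0.46, 1.45 with total-count scaling (camera, adjusted p = 0.00162, and 0.887 with an estimated correlation), with IDH2 and DLST at 0.90 and 1.04 and none passing. Their medians within pigs overlapped, at 0.52, -0.35 and -0.76 in SCS pigs 1, 3 and 5 and 0.12, 0.18 and 0.68 in HOPE pigs 2, 4 and 6.

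Without the block limma called 0 genes for the difference at 48 h (510 at an unadjusted p under 0.05), and SESN3 (-1.32), BLTP2 (1.01) and S100A11 (-1.21) had the smallest p (limma, adjusted p = 0.988). edgeR called 0 without the block and 9 with it, and DESeq2 called 0. At 12 h, at 24 h and for the mean over the 3 times limma called 0 with and without the block (82, 260 and 316 at an unadjusted p under 0.05 without it), and edgeR and DESeq2 called 0. The smallest p belonged to RIMBP2 (-2.71), PTPRZ1 (2.01) and HBB (4.08) at 12 h, to MRGBP (-1.19), RIMBP2 (-2.61) and SERPINE2 (-1.04) at 24 h, and to MRGBP (-0.96), S100A11 (-0.92) and HBB (3.64) for the mean. The blocked count of 18 at 48 h became 259 without pig 1, 49 without pig 3 and 0 without pig 2, 4, 5 or 6.

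After NMP, hearts stored for 24 or 48 h of HOPE had higher levels of inflammatory and interferon-induced genes than hearts stored for 3 h, as lists. Inflammatory mediators had a median of 1.29 at 24 h and 1.35 at 48 h, with 13 of 13 positive at both times (camera, adjusted p = 9.95e-06 and 3.04e-11; 0.782 and 0.728 with an estimated correlation), and 10 and 9 of 13 higher adjusted over the list alone. The platelet and endothelial adhesion protein SELP was at 1.83 and 1.98, the neutrophil chemokine CXCL2 at 2.28 and 3.38, the adhesion proteins VCAM1 and ICAM1 at 1.28 and 1.29 at 24 h, and PTGS2 and CXCL8 at 2.39 and 2.61 at 48 h. Interferon-induced genes had medians of 1.17 and 1.34 (camera, adjusted p = 4.09e-06 and 2.36e-12; 0.638 and 0.242 with an estimated correlation), with 11 and 10 of 12 higher adjusted over the list alone. The antiviral genes IFIT1, MX2, RSAD2 and IFIH1 were at 1.15, 2.11, 1.64 and 1.41 at 24 h, and IFIT1, IFIT2, RSAD2 and OAS2 at 1.91, 2.16, 2.07 and 1.42 at 48 h. Extracellular matrix genes had a median of 0.91 at 24 h (camera, adjusted p = 1.35e-05; 0.782 with an estimated correlation), with 11 of 16 higher adjusted over the list alone, among them COL5A2 at 1.18, FN1 at 1.24, THBS1 at 1.54 and MMP2 at 1.07. Tricarboxylic acid cycle genes had a median of -0.33 at 24 h (camera, adjusted p = 1.6e-05; 0.782 with an estimated correlation), with IDH3B at -0.66, MDH1 at -0.77 and DLST at -0.53 and 0 adjusted over the list alone. Immediate-early genes had a median of 1.07 at 48 h (camera, adjusted p = 2.28e-07; 0.728 with an estimated correlation), with FOSL1 at 1.93, ATF3 at 1.37, EGR1 at 1.09 and BTG2 at 1.51 and 0 adjusted over the list alone. No member of these lists passed over all genes without the block. The 3 h group is 2 libraries, and the second stood apart on the second principal component (38.7, against -17.9 to 5.95 in the other 6), with CXCL2 at 35.5 TPM against 83.2 and SERPINB2 at 90.8 against 752. Against the first and the second 3 h library alone, the inflammatory median was 1.05 and 1.55 at 24 h and 1.18 and 1.74 at 48 h. The interferon median was 1.06 and 1.24, then 1.25 and 1.52, the matrix median 0.59 and 1.32 at 24 h, and the immediate-early median 0.57 and 1.51 at 48 h. Fibroblast markers were at 0.70 and 0.87 at 24 h and 0.54 and 0.64 at 48 h. Endothelial markers were at 0.34 and 1.38 at 24 h and -0.23 and 0.55 at 48 h. Whether cell make-up accounts for the list differences was not tested.

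**Figure D3:**
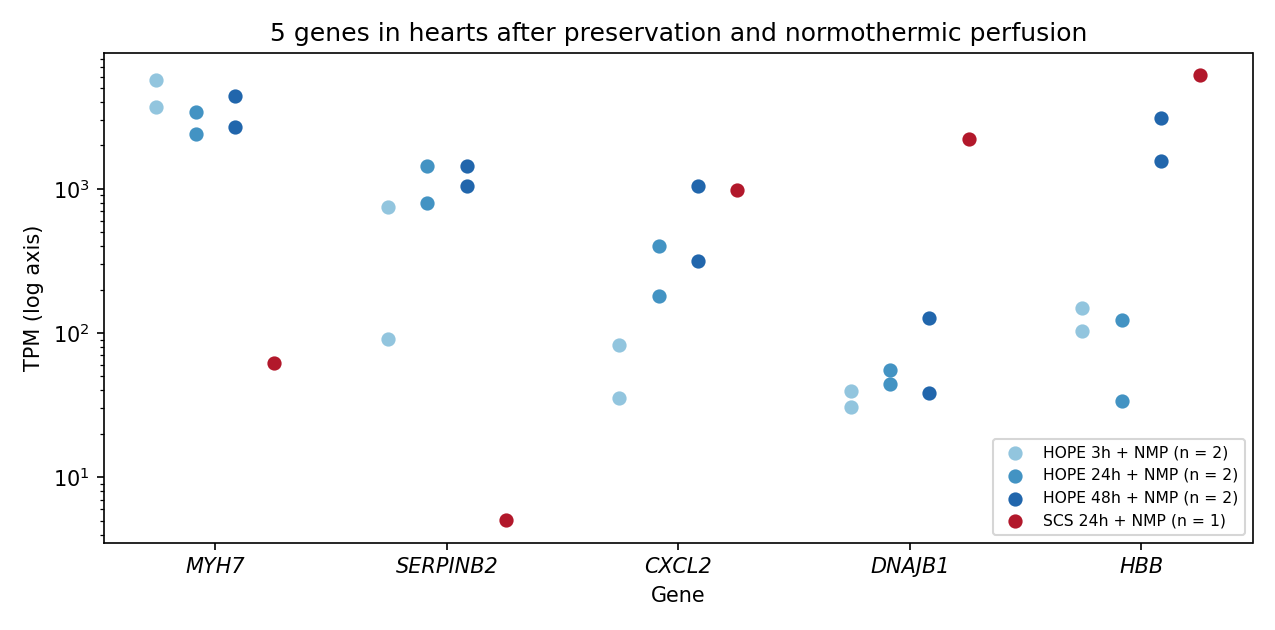
Levels of 5 genes in TPM on a log axis, 1 point per library, in hearts after 3, 24 or 48 h of HOPE or 24 h of SCS, each followed by NMP. MYH7 stood at 62.0 TPM in the SCS library against a mean of 2902 in HOPE at 24 h, and DNAJB1 at 2225 against 49.8.

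Over all genes limma without the block called 0 for HOPE 24 h against 3 h (663 at an unadjusted p under 0.05) and 0 for 48 h against 3 h (354); no other tool was run on TPM. With the second 3 h library alone as the 3 h group, the 24 h count was 39. Genes among the smallest p were AMOTL2 (1.87) and CTGF (3.20) at 24 h, with limma adjusted p of 0.208, and HBB (4.13), ALAS2 (3.45) and IFIT1 (1.91) at 48 h, with 0.167. Between 48 and 24 h of HOPE, limma called 3 genes, all higher at 48 h. HBB was higher by 5.05 ± 0.60 (limma, adjusted p = 0.0428), with 79.1 ± 64.1 TPM at 24 h and 2322 ± 1080 at 48 h (SD, n = 2). The 2 others were named after their values were seen. ALAS2 was higher by 4.23 ± 0.51 (limma, adjusted p = 0.0428) and the unnamed gene ENSSSCG00000007978 by 5.04 ± 0.48 (limma, adjusted p = 0.0218). Endothelial markers had a median of -0.52 between 48 and 24 h (camera, adjusted p = 0.0159; 0.903 with an estimated correlation), with KDR at -1.26, EGFL7 at -0.89, ROBO4 at -1.08 and FLT1 at -0.76. Adjusted over the list alone 1 endothelial marker was lower and over all genes 0. The call of 3 genes became 0 to 5 when 1 library was left out, and 0 with quantile normalization or without the filter.

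The single SCS 24 h heart after NMP differed widely from the 2 HOPE 24 h hearts after NMP, with contractile and metabolic genes lower and interferon, red cell, some chaperone and some immediate-early genes higher. Its comparison has no SCS replicate: it borrows the spread of the HOPE groups and compares this library, not the condition. For this library, fell and rose mean lower or higher than in the HOPE 24 h libraries after NMP. The median over all genes was -1.12. It was -0.159 when rescaled without the mitochondrial and the 2 most abundant other genes, and -0.122 with quantile normalization. Fold changes given for this library include this shift, and the endothelial median of -1.11 was about equal to it. Ventricular cardiomyocyte markers were lower as well (median -3.14) and fibroblast markers higher (median 1.40). Fewer cardiomyocytes in the sample therefore cannot be told apart from lower levels within them. All 17 sarcomere genes tested fell, with a median of -4.70 (camera, adjusted p = 1.48e-09; 0.411 with an estimated correlation), among them the troponins TNNI3 and TNNT2 at -4.05 ± 0.26 and -4.48 ± 0.33, cardiac actin ACTC1 at -5.09 ± 0.36 and actinin ACTN2 at -5.34 ± 0.40. The beta myosin heavy chain MYH7 fell by 5.51 ± 0.43, from 2902 ± 690 TPM (SD, n = 2) to 62.0 TPM (limma, adjusted p = 0.000317), and may share reads with its paralog MYH6. The muscle proteins FLNC, CSRP3 and LMOD2 changed by -6.999, -6.26 and -5.63, the cardiac stress protein ANKRD1 by -6.50 and the protease inhibitor SERPINB2 by -7.49 (limma, adjusted p = 0.000341, 0.000327, 0.000271, 0.000336 and 0.00122). All 23 nuclear-encoded respiratory chain genes fell, with a median of -3.47 (camera, adjusted p = 1.17e-07; 0.507 with an estimated correlation) and NDUFS7, COX4I1, COX5B and NDUFA4 at -3.97, -3.42, -3.82 and -3.80. Of the tricarboxylic acid cycle, fatty acid and calcium handling genes, 17 of 17, 12 of 13 and 9 of 10 fell, with medians of -3.07, -3.31 and -3.26 (camera, adjusted p = 5.95e-05, 0.000952 and 0.000575; 0.507, 0.507 and 0.411 with an estimated correlation). Cardiac stress genes had a median of -3.68 and were not called by camera. Unfolded protein and integrated stress response genes had a median of -0.46, above the median of -1.12 over all 4388 genes. It lay at percentile 98.35 of 10000 random lists of like size and expression.

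In the same library the chaperone genes DNAJB1 and HSPH1 rose by 5.46 ± 0.64 and 4.44 ± 0.40, with DNAJB1 at 2225 TPM against 49.8 ± 7.43 (SD, n = 2; limma, adjusted p = 0.000687 and 0.000336). Heat shock proteins had a median of 0.57 with 5 higher and 3 lower (camera, adjusted p = 2.15e-08; 0.411 with an estimated correlation), the muscle chaperones HSPB8 and DNAJB5 passing at -4.33 and -4.37. The immediate-early gene FOS rose by 3.98 ± 0.97, the transcription factor IRF1 by 2.18 ± 0.64 and PPP1R15A, of the integrated stress response, by 1.85 ± 0.53 (limma, adjusted p = 0.0113, 0.0227 and 0.0209). Immediate-early genes had a median of 0.89 with 4 higher and 1 lower (camera, adjusted p = 1.45e-08; 0.411 with an estimated correlation), KLF4 and EGR2 passing at 2.75 and 1.97 and IER3 at -3.89. Interferon-induced genes had a median of 1.61 with 8 of 12 higher, among them IFIT1, OAS2, IFI44L and MX1 at 2.19, 1.93, 1.60 and 2.32 (camera, adjusted p = 6.36e-18; 0.142 with an estimated correlation). Fibroblast markers had a median of 1.40 with 5 of 6 higher, among them the collagens COL1A2 and COL3A1 at 1.63 and 1.58, C7 at 2.168 and DCN at 1.13 (camera, adjusted p = 1.1e-09; 0.344 with an estimated correlation). HBB rose by 6.54 ± 0.74 to 6134 TPM (limma, adjusted p = 0.000607), and HBM and ALAS2 by 5.33 and 4.17. Of the endothelial markers 5 fell, among them KDR, VWF, FLT1 and PECAM1 at -2.02, -1.97, -1.83 and -1.43; the list median of -1.11 had a camera adjusted p of 0.809. Mitochondrially encoded genes had a median of 0.20, -0.11 with quantile normalization (camera, adjusted p = 6.49e-07; 0.411 with an estimated correlation).

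Limma called 106 genes higher and 2272 lower in this comparison, and the median over all 4388 genes was -1.12. Among 10000 random lists of like size and expression, the sarcomere, respiratory chain and fatty acid medians lay at percentile 0. The tricarboxylic acid and calcium medians lay at 0.04 and the heat shock median at 99.99. The fibroblast, interferon and immediate-early medians lay at 100 and the endothelial median at 56.97. Cardiac stress genes also lay at 0.04, and inflammatory and extracellular matrix genes at 100. Genes of the random lists were drawn independently, so members that vary together can place a list at either end. The percentiles are therefore no test of a list. In the SCS library 2 unnamed genes, ENSSSCG00000025162 and ENSSSCG00000021356, held 9.52% and 6.01% of all TPM, against at most 1.42% and 0.957% in the HOPE libraries. Rescaled without these and the mitochondrially encoded genes, the count was 1391 with 27.7% higher, against 4.46% before, and quantile normalization gave 1415 with 37.2% higher.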

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

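All the tests of explanations below were chosen only after the result they weigh had been seen; the counts of other splits of the samples were planned. What marked the 18 genes and 7 lists of the next paragraph was a difference between HOPE and SCS in the change from 0 to 48 h, tested directly. The patterns after them were picked once their values had been seen.

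With the pig as a replicate block, limma called 18 genes for this difference. By list, camera at the preset correlation called mitochondrially encoded genes (median -1.76, -0.77 with total-count scaling), tricarboxylic acid cycle genes (0.46), fatty acid genes (0.53, adjusted p = 0.0333) and macrophage markers (0.74, adjusted p = 0.00519). With total-count scaling the fatty acid list (1.52, adjusted p = 0.526) and the macrophage list (1.73, adjusted p = 0.0866) did not pass. It also called 3 lists whose median changed sign with total-count scaling: ribosomal proteins (-0.58, then 0.41), SR proteins of splicing (-0.22, then 0.77; adjusted p = 0.0206) and T and NK markers (-0.65, then 0.29; adjusted p = 0.032). The camera adjusted p with an estimated correlation was 0.887 for all 7 lists. Medians within pigs overlapped between SCS and HOPE for the tricarboxylic acid, fatty acid, macrophage and SR protein lists. Fatty acid medians were -0.66 to 0.55 in SCS and 0.09 to 0.72 in HOPE, and macrophage medians -1.11 to 0.68 and -0.10 to 0.56. They did not overlap for mitochondrially encoded genes, ribosomal proteins and T and NK markers. ETFA and ITGAM, at 1.09 and 1.07, and SRSF4 and GNLY, at -0.48 and -1.65, led the 4 lists not described before, and none passed with limma over all genes (adjusted p = 0.988).

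The first pattern was the rising share of mitochondrially encoded transcripts in SCS hearts. The 48 h library of pig 5 as the whole source was argued against by the other pigs, whose smaller rise was 12.2 points. More cardiomyocytes in the later biopsies were argued against in pigs 3 and 5 by 55 sarcomere and nuclear-encoded respiratory chain genes, whose higher median was -0.13 and of which 0 reached the lowest mitochondrial gene; in pig 1 this stays open, with a median of 0.59 and an upper quartile of 0.69 against a lowest mitochondrial gene of 0.80, which 10 of the 55 reached. A loss of other RNA while mitochondrial RNA remained cannot be told apart from a gain of mitochondrial RNA, since both give the median of -0.991 over all genes with total-count scaling, and no measure of RNA amount per cell was used here. A biological effect of storage stays open and untested.

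The second pattern was HBB and ALAS2 in HOPE hearts after 0 h. A single library was argued against, because 9 of 9 such libraries had more HBB than each of the other 15. ALAS2 was also above every other library in 9 of 9, so red cells may account for it, but whole blood and red cells without white cells cannot be told apart. T and NK markers had a median of -0.93 at 48 h of HOPE and macrophage markers of 0.21, yet the T and NK markers already stood at a median of 67.3 normalised counts at 0 h against a gain of 120 in the group median of HBB, which would hide a small share of blood. A biological effect of HOPE stays open and untested, and the make-up of the perfusate was not used here.

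The third pattern was a profile of mitochondrial transcripts that differed between pigs: ND1 took 1.13% to 1.3% of mitochondrial counts in pigs 1, 3 and 6 and 3.63% to 4.44% in pigs 2, 4 and 5. Preservation method or time as the cause was argued against by the 0 h libraries, where the highest ND1 share was at least 3.38 times the lowest within each condition. A mitochondrial sequence variant against the reference cannot be told apart from other lasting differences between pigs: that 6 of 6 pigs kept their side at all 4 times restates the pattern, and no read sequences were used here. No biological explanation was tested.

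Other splits of the 6 libraries of a comparison, 10 in each case, are too few for a share under 0.05. For HOPE against SCS at 48 h the 884 genes were matched or exceeded in 2 of 10 splits, the real one included, with 2094 in the highest other. At 24 h 2 of 10 splits did so, with 299 against 288, at 12 h 3 of 10, with 8 against 2, and at 0 h 10 of 10, with 25 against 0. For SCS 48 h against 0 h without the block 10 of 10 did, with 2 against 0, and for all other changes and differences 10 of 10 did, with 0 against 0. In each comparison of HOPE with SCS the highest other split parted pigs 1, 2 and 4 from pigs 3, 5 and 6. With the block, the sign flips of single pigs gave at most 24 genes against 308 for SCS 48 h and 0 against 1 for HOPE 48 h, over 4 splits each, and the other splits 0 against 18 for the difference at 48 h, over 10.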

How the results depend on the processing

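The combinations of the block with edgeR or with a left-out pig, the single left-out libraries, the minimum of 1 TPM and the rescaling were tried only after the data were seen. Of all the alternative gene values 3732 kept their direction and their side of the threshold, 227 gained and 229 lost the call and 6 changed sign; of list values 102 kept both, 79 lost the call and 7 changed sign. Without the block, no list described in the Results as called at the preset correlation passed with an estimated correlation. With the block added as well, T and NK markers in HOPE passed at some times and not at others. The list calls therefore rest on the preset correlation, and not only on the scaling. Of the counts 256 stayed within 1.5 times and 86 did not. The cause was not tested unless the alternative itself gives it. Total-count scaling shifted all nuclear genes, with a median of -0.991 for SCS 48 h and 1.122 for HOPE against SCS at 48 h. It moves nothing in arm 2. Quantile normalization is void for the most abundant genes, whose values it sets by their rank alone. Depth limits the SCS 48 h library of pig 5 most, since 82.4% of its reads were mitochondrial, and depth in arm 2 is unknown.

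Counts of genes moved as follows. Without the filter: SCS 48 h 8, HOPE against SCS 2 at 0 h and 114 at 24 h, HOPE 48 h against 24 h after NMP 0. Total-count scaling: SCS 48 h 5553, HOPE against SCS 1, 4 and 8122 at 12, 24 and 48 h. Quantile normalization: HOPE against SCS at 24 h 116, HOPE 48 h against 24 h after NMP 0, SCS against HOPE after NMP 1415. Only the groups compared: HOPE against SCS 0, 0 and 0 at 12, 24 and 48 h, and after NMP HOPE 48 h 4 against 3 h and 0 against 24 h. Replicate block: SCS 48 h 308, HOPE 48 h 1, their difference 18. For HOPE against SCS, where it is a single correlation shared by all genes, it gave 6, 1396 and 1628 at 12, 24 and 48 h. After NMP, where pairing of equal numbers could not be decided, it gave 28 for HOPE 24 h and 29 for 48 h against 3 h. Among these were 4 and 6 inflammatory and 1 and 4 interferon-induced genes, with CXCL2 at adjusted p = 0.0467 and 0.00609 (limma with the block). edgeR with the replicate block: 173 for SCS 48 h, 1 for HOPE 48 h, 9 for their difference. DESeq2: SCS 48 h 22, HOPE 4 at 24 h and 2 at 48 h, HOPE against SCS 11, 86, 1521 and 1931 at 0, 12, 24 and 48 h. For HOPE 48 h after NMP against 24 h, a pseudocount of 0.5 gave 1, a mean of at least 1 TPM 0 and rescaling 0; against 3 h, a pseudocount of 5 gave 1 and a mean of at least 50 gave 1. SCS against HOPE after NMP gave 827 with a mean of at least 50 and 1391 with rescaling.

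Leaving out 1 pig gave 0 to 337, 0 to 1432, 2 to 2721 and 5 to 3282 for HOPE against SCS at 0, 12, 24 and 48 h, and 0 to 1 for SCS 48 h. With the replicate block as well it gave 0 to 597 (329 without pig 1) for SCS 48 h, 0 to 2 for SCS 24 h, 0 to 1 for HOPE 24 h, 0 for HOPE 48 h, 0 to 259 (49 without pig 3) for the difference at 48 h and 0 to 45 for the mean difference. Without the 0 h library of pig 6, HOPE against SCS at 0 h gave 12, and HOPE at 12 and 24 h with the replicate block 1 and 1; without the 48 h library of pig 5, HOPE against SCS at 48 h gave 14. After NMP, leaving out 1 library gave 0 to 39 for HOPE 24 h and 0 to 6 for 48 h against 3 h, 0 to 5 for 48 h against 24 h, and 1253 to 2550 for SCS against HOPE.

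Signs turned with total-count scaling for ribosomal proteins (-0.56 in SCS 48 h, 0.16 in HOPE against SCS at 48 h, 0.41 in the difference), coagulation genes in HOPE against SCS at 48 h (0.96), and SR proteins (0.77) and T and NK markers (0.29) in the difference. Lists that kept sign and call but moved by over 1.5 times with it were, in SCS 48 h, endothelial markers (-1.72), in HOPE against SCS ribosomal proteins (-0.199, -0.339 and -0.466 at 0, 12 and 24 h), T and NK markers at 12 h (-0.854), tricarboxylic acid (2.04) and calcium handling genes (2.09) at 48 h, and in the difference tricarboxylic acid genes (1.45). For genes signs turned in SCS 48 h for RPL14 (-0.31), RPL24 (-0.31), RPL35 (-0.19) and RPS25 (-0.46) and in the difference for RPL38 (0.034). With quantile normalization they turned for mitochondrially encoded genes in SCS against HOPE after NMP (-0.11) and for ND4 in SCS 48 h (-0.029).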

Other observations

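Cardiac stress genes had a median of 0.50 at 24 h of SCS (camera, adjusted p = 0.000294; adjusted p = 0.634 with an estimated correlation) and extracellular matrix genes of 0.27 (camera, adjusted p = 2.2e-05; adjusted p = 0.753 with an estimated correlation). Glycolysis genes had a median of 1.04 in HOPE against SCS at 48 h, with 4 of 22 higher and 1 lower (camera, adjusted p = 0.000612; adjusted p = 0.526 with an estimated correlation). In the SCS library after NMP, glycolysis genes had a median of -2.58 with 11 of 15 lower (camera, adjusted p = 0.017; adjusted p = 0.557 with an estimated correlation), and ventricular cardiomyocyte markers of -3.14 with 5 of 5 lower (camera, adjusted p = 0.0148; adjusted p = 0.451 with an estimated correlation).

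Mitochondrially encoded genes took 39.8% to 51.1% of TPM in the single HOPE libraries after NMP and 54.7% in the SCS library. Ribosomal protein genes made up 3.96% of the nuclear counts at 0 h and 4.71% at 48 h of SCS, and 3.21% and 2.73% in HOPE. At least 1 read was recovered for 17240 to 18599 genes per arm 1 library, and the first 2 principal components held 37.6% and 10.6% of the variance.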
